A study of Mus musculus with 4 samples.

How the data were processed

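Maternal blood cells and decidual nuclei of pregnant mice at gestational day 10.5 were measured by droplet RNA sequencing (10x Genomics). There were 4 libraries, 1 for each combination of tissue (blood, decidua) and genotype (Swiss Webster wild type, WT, or heterozygous for the serotonin-1A receptor, Het). Each blood library was a pool of 4 females and each decidua library a pool of 3 deciduae. For blood, a mononuclear fraction and a granulocyte fraction were prepared apart, treated with red cell lysis buffer and recombined. Per the labels, the Het deciduae came from F1 placentas. The pooling left no replicates, so no test between genotypes was run and no p-value for a genotype difference is given.

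The deposited matrices hold raw counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, for all barcodes, with no cell calling. Per the file headers they were written by Cell Ranger 4, while the submitters' processing notes list Cell Ranger 5.0.0 and Cell Ranger 6.0.0. The genome build was mm10. Neither the annotation release nor the handling of intronic reads was stated. The matrices list 32285 genes, of which 32158 were given positions from the GENCODE vM21 annotation by their Ensembl identifiers.

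The whole libraries held 212559392 UMIs (blood WT), 231090895 UMIs (blood Het), 94414986 UMIs (decidua WT) and 83756236 UMIs (decidua Het). A barcode counted as a cell or nucleus with at least 500 UMIs in blood or 1000 UMIs in decidua and at least 200 genes, provided that it passed 1 of 2 criteria. Its UMIs lay above 10% of the 99th percentile of the 3000 largest barcodes (cuts of 2154.2, 2183.62, 2552.54 and 2162.37 UMIs in blood WT, blood Het, decidua WT and decidua Het), or it differed from the library's free RNA profile in a Monte Carlo multinomial test at an adjusted p of 0.001. The free RNA profile was the sum of barcodes with 100 or fewer UMIs. The test used 100000 simulated draws, raised after a first run in which the smallest possible p was too coarse for an alternative with many candidate barcodes. Barcodes with over 10% (blood) or 5% (decidua) mitochondrial UMIs were removed. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed. Scrublet marked 252 barcodes (2.52%) of blood WT but only 6 (0.0451%) of blood Het, and 701 (6.60%) and 857 (6.84%) of decidua WT and Het. Doublet removal was therefore unequal between the blood libraries.

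For clustering, both libraries of a tissue were combined without haemoglobin, mitochondrial, receptor segment, Xist and Y-linked genes. Values per 10000 UMIs were log transformed and 2000 variable genes, chosen across both libraries, were reduced to 30 components. A shared-neighbour graph of 15 neighbours was partitioned with leidenalg 0.10.2 at resolution 1. No correction between libraries was applied, since library and genotype were the same split. Clusters were named by marker lists fixed before the data were examined, but the limits of the naming rule were set after the marker scores of the first clusters were seen. A marker counted when some cluster held at least 50 CPM (UMIs of a gene per 1000000 UMIs) and at least 4 times its level in low clusters. A class needed 3 detected markers and a mean relative level of at least 0.4, with the next class at or below 0.75 of it. A cluster also stayed unnamed when its leading genes held more markers of another class, or when it had few informative markers or few UMIs and no own marker among its leading genes. The condition on few informative markers was added last, when it left a cluster led by cell cycle genes unnamed. Shares of unnamed clusters are given with the others. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, numba 0.67.0 and matplotlib 3.10.9 were used, with random seed 1.

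Class shares were taken of all kept cells with exact 95% Clopper-Pearson intervals, and their Het over WT ratios with conditional exact intervals. For expression, UMIs were summed over a class in each library and scaled to CPM, and the log2 ratio of Het over WT was taken with 0.5 added to each count. A class needed 100 cells in each library. The fixed design scaled by class totals, with the median gene ratio set to 0 as its alternative. Since that median was then seen to lie further than 0.1 from 0 in several classes, the reported log2 ratios are relative to the median of all genes in the class, and ratios of plain class totals are given as the alternative. The shift was 0.18 in blood neutrophils, -0.10 in T cells, 0.03 in monocytes or macrophages and -0.10 in all blood cells, and within 0.01 of 0 in the decidual stromal, endothelial and NK classes and in all nuclei. Without haemoglobin genes the neutrophil shift was -0.44. Intervals cover counting error only, not differences between animals, pools or preparations. For a count of 0 the limit given is that of 3 UMIs.

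Gene lists, 25 in all and 20 of them for blood, were fixed before the data were examined. In each of the 3 largest named classes of a tissue and in all kept cells, the median log2 ratio of members with 10 or more UMIs was given with its percentile among 10000 random lists of the same size matched on expression. The percentile describes these libraries and is no test between genotypes. A member is called higher or lower by size only: at least 1.5-fold with an interval off 1. Named genes needed 30 UMIs over both libraries and 50 CPM in at least 1 of them and were ranked by the bound nearest to 0, with 5 in each direction named per class. Haemoglobin, mitochondrial, immunoglobulin and receptor segment, Xist and Y-linked genes and unnamed gene models were left out of the rank. So were genes below the free RNA level whose ratio there went the same way and was at least as large. Up to 4 members of each described list with the bound farthest from 0 were eligible to be named as well. Other genes named in the text were chosen after their values were seen. The minimum of 10 members for a list to lead a class, which decides the list alternatives printed in full, was also set after first values were seen.

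The procedure was tested on simulated data. Changes of 2-fold and 4-fold placed on 200 genes were called by the size rule for 197 to 200 genes in each of 3 classes, and changes of 1.5-fold for 91 to 107 genes. Among 3933 unchanged genes of decidual NK nuclei, 33 to 53 were called by the size rule, against 0 in each of the other 2 classes. An unchanged list of 20 genes reached percentile 1.08 in NK nuclei. The 95% intervals covered the true ratio for 93 to 98% of genes. Counts of both libraries were drawn as Poisson counts from 1 profile per class, apart from the placed changes. The simulation held no variation between cells, animals, cluster mixes or free RNA, so its coverage and its calls of unchanged genes describe counting error only. Of 1000 simulated empty barcodes per library 0 were called as cells, and of 1000 simulated shallow cells 439, 481, 611 and 636 were called in blood WT, blood Het, decidua WT and decidua Het. The empty barcodes were drawn from the same free RNA profile that the calling test uses. Their 0 calls therefore say nothing about real empty barcodes that differ from that profile.

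The alternatives chosen before the data were examined were a lower and a higher UMI minimum (250 and 1000 in blood, 500 and 2000 in decidua), the UMI cut alone, the UMI minimum with no free RNA test, a lower mitochondrial limit, no doublet removal, resolutions of 0.5 and 2, separate clustering of each library, plain class totals, other count minimums, an added count of 2, subtraction of free RNA, and thinning of the deeper library. Added after the data were seen were removal of the top 8% of doublet scores in each library, clustering without granule genes, named leukocytes or non-trophoblast nuclei as denominator, cells with under 50% haemoglobin UMIs, scaling by UMIs without haemoglobin genes, and the interferon list without 3 genes of chromosome 1. No reads were available, so mapping was not repeated.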

Results

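Maternal blood was profiled by single-cell sequencing and decidua, the maternal tissue around the implanted embryo, by single-nucleus sequencing, each in 1 pooled WT and 1 pooled Het library at gestational day 10.5. Het females carried a heterozygous loss of Htr1a, which encodes the serotonin-1A receptor, an inhibitory G protein-coupled receptor. The comparisons ask how maternal immune cells in the circulation and cells at the maternal-fetal interface differed between the genotypes. After filtering, 9738 cells of blood WT, 13298 cells of blood Het, 9926 nuclei of decidua WT and 11667 nuclei of decidua Het were kept. Their median UMIs were 4650.5, 5496.5, 3740.5 and 2703, and their median genes 595, 841, 1670 and 1317. Haemoglobin genes took 85.2% of all UMIs in blood WT and 81.1% in blood Het, and a median of 62.7% and 58.5% of the UMIs of a kept cell. There were no replicates, so differences between the libraries are given as values with counting error and were not tested against the spread between animals.

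The target gene was barely detected. Kept blood cells held 0 Htr1a UMIs in WT, which allows up to 0.0569 CPM, and 9 in Het (0.111 CPM, 95% interval 0.0508 to 0.211). Kept nuclei held 0 in decidua WT, which allows up to 0.0655 CPM, and 2 in decidua Het (0.0502 CPM, 0.00607 to 0.181). Over all barcodes there were 3 UMIs in blood WT, 11 in blood Het, 0 in decidua WT and 4 in decidua Het, so the few UMIs lay mostly in Het, opposite to the genotype label, and no lower Htr1a level in Het was seen. The serotonin genes with most UMIs were Slc6a4, the serotonin transporter, in blood, at 28.6 CPM in WT and 19.97 CPM in Het (log2 ratio -0.42, -0.52 to -0.31), and Tdo2 and Htr2b in decidua. Slc6a4 was a leading gene of the platelet cluster, lower in Het (6.71% and 3.81%), and of an unnamed cluster that was higher in Het (6.45% and 8.11%), and within named platelets it stood at 328 and 356 CPM (-0.04). Tdo2, which degrades tryptophan, stood at 354 and 320 CPM and Htr2b, the serotonin-2B receptor, at 61.2 and 53.6 CPM in WT and Het. Maob, a monoamine oxidase, was at 14.6 CPM in decidua WT and 5.32 CPM in Het, and the tryptophan-degrading genes Ido1 and Ido2 were at 7.10 and 2.53 CPM and at 17.0 and 6.85 CPM. The serotonin list had a median log2 ratio of -0.16 in all decidual nuclei (20 members measured, 4 lower, percentile 1.67) and -0.05 in all blood cells (7 members, percentile 48.8). In decidual endothelial nuclei its median was -0.52 with 10 members, none of them higher or lower by the size rule (percentile 1.10).

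In blood, neutrophils made up a smaller share of the Het library and T cells, NK cells and erythroid cells a larger one. Neutrophils were 43.8% of WT cells (95% interval 42.8 to 44.7) and 29.3% of Het cells (28.5 to 30.1), a log2 ratio of -0.58 (-0.64 to -0.52). T cells were 19.5% and 25.9% (0.41, 0.33 to 0.49), NK cells 3.48% and 4.32% (0.31, 0.11 to 0.51) and erythroid cells 3.17% and 10.8% (1.77, 1.59 to 1.95). Of the blood barcodes that met the UMI minimum, 57339 in WT and 58454 in Het, only 10281 and 13624 also met the gene minimum. The erythroid share therefore counts only cells above the gene minimum and is no measure of all red cells. No alternative changed the gene minimum. Named platelets were 6.71% and 3.81% (-0.81, -0.98 to -0.65), while an unnamed cluster led by the platelet genes Itga2b, Parvb and Thbs1, which scored close to erythroid cells as well, held 6.45% and 8.11%. The platelet ratio therefore depends on which of these clusters was named. B cells were 5.70% and 5.36%, monocytes or macrophages 7.48% and 7.80%, basophils or mast cells 0.298% and 0.218%, plasma cells 0.113% and 0.0677%, and unnamed clusters 9.82% and 12.4%. Of named leukocytes alone, which leaves out erythroid cells and platelets, neutrophils were 54.5% and 40.2% and T cells 24.3% and 35.5%. Both denominators include neutrophils, so a smaller neutrophil share by itself raises the T and NK cell shares. Neutrophils numbered 4261 of 9738 WT and 3896 of 13298 Het cells, T cells 1897 and 3445, and NK cells 339 and 574. Shares outside neutrophils were not taken. Within T cells, a CD8 cluster led by Cd8b1, Cd8a and Gzmm held 2.24% of WT and 4.11% of Het cells, and a regulatory cluster led by Foxp3, Ikzf2 and Ctla4 held 2.13% and 1.77%. The 2 blood fractions were recombined before loading, so the neutrophil to lymphocyte ratio also carries the recovery of each fraction. When each library was clustered on its own, the platelet ratio turned to 0.31, the erythroid ratio was 0.78 and the B cell ratio -4.05.

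**Figure D1:**
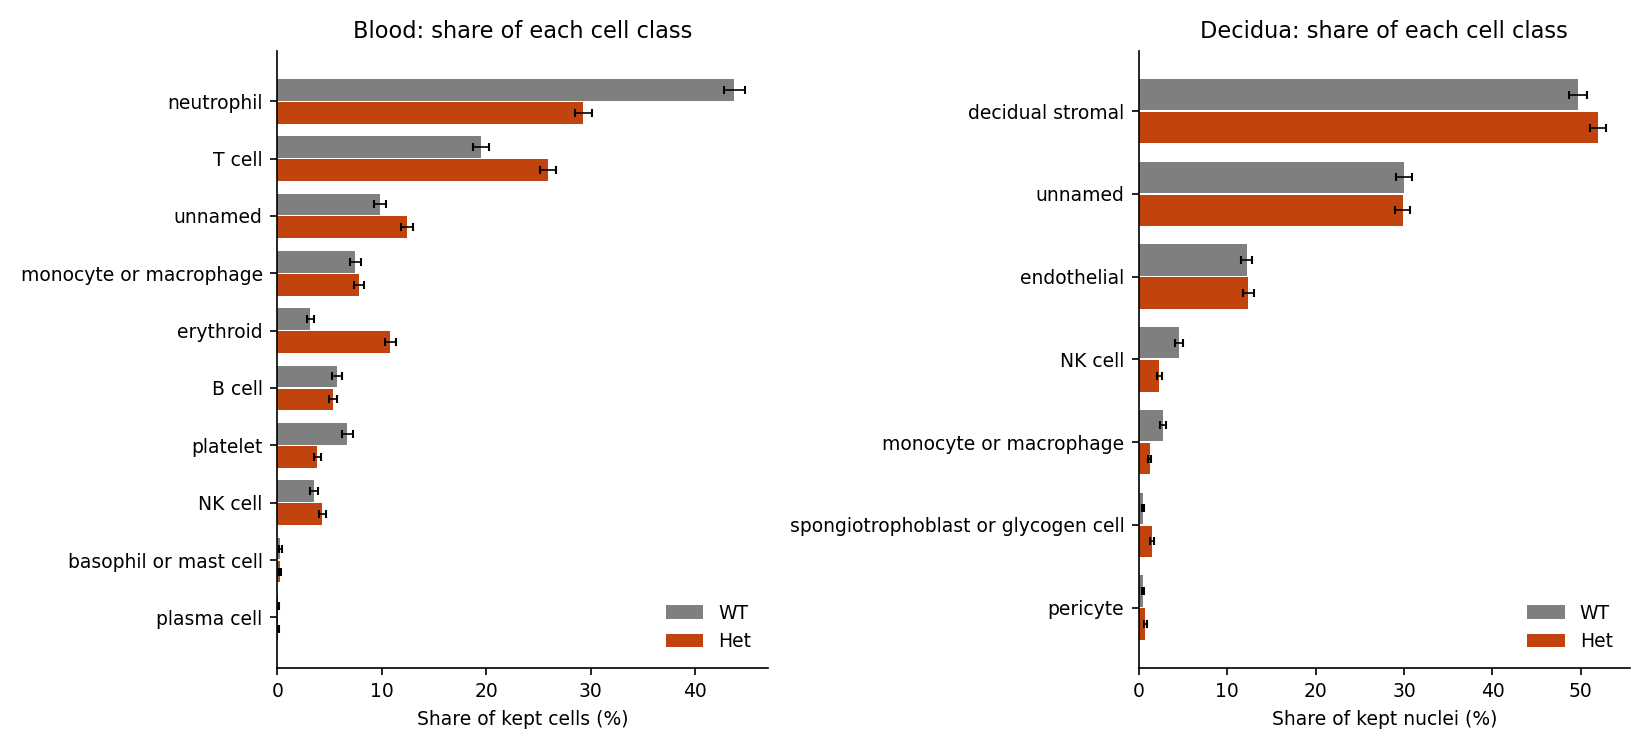
Share of kept cells or nuclei (percent) in each named class, and in unnamed clusters, of blood and decidua, for the WT and Het libraries. Bars are the shares of 1 pooled library each and error bars their 95% Clopper-Pearson intervals. Blood neutrophils are lower in Het (43.8% to 29.3%) and T cells higher (19.5% to 25.9%), and decidual NK cells are lower in Het (4.51% to 2.31%).

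Het blood neutrophils carried much higher levels of granule genes than WT neutrophils. The secondary and tertiary granule list had a median log2 ratio of 1.87 (percentile 100). Its members' lower and upper bounds had medians of 1.76 and 2.01. All 18 members were higher in Het. They included Ltf (lactoferrin, 116 to 624 CPM), Retnlg (2041 to 11066 CPM), Ngp (420 to 2014 CPM) and Lcn2 (563 to 2765 CPM), products that neutrophils load into granules during maturation. The genes named as highest were Prok2, a secreted chemoattractant, at 8.42 and 443 CPM (5.53, 5.29 to 5.79), the cystatin-like Stfa2 (3.85) and Cstdc5 (3.04), the membrane protein gene Ifitm6 (3.10) and the neutrophil surface gene Ly6g (2.67, 35.2 to 255 CPM). Those named as lowest were Sntb2 (-1.35), Cxcr4, the receptor that retains neutrophils in bone marrow (-1.27, 178 to 83.8 CPM), Kif23 (-1.11), the inflammatory cytokine Il1b (-1.07, 1277 to 692 CPM) and Tnfaip2 (-1.03).

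The granule genes marked 2 clusters of neutrophils, 1 led by Prok2, Cstdc5 and Ly6g and 1 led by Camp, Ltf and Ngp. Together these held 192 of the WT neutrophils (4.51%) and 1722 of the Het neutrophils (44.2%). Inside these clusters the list median was -0.07 (18 members, 5 higher and 5 lower, percentile 0, against 0.13 to 0.51 for random lists). These clusters were formed with granule genes among others, so the split itself largely sets the median inside them. In the other neutrophil clusters it was 0.78 (16 members measured, 11 higher, percentile 100). A cluster led by the interferon-induced genes Oasl1, Ifit1 and Cmpk2 held 3.32% of WT and 1.61% of Het blood cells.

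Other lists separated in the same cells. Granule-led clusters held 4.51% of WT and 44.2% of Het neutrophils, so the mix of clusters enters these medians and the named genes. The hypoxia and glycolysis list had a median of 0.95 (22 members, 15 higher and 2 lower, percentile 100), with the glycolytic enzymes Gapdh (216 to 674 CPM, log2 1.46), Pgk1 (1.39) and Ldha (1.36) higher, while the hypoxia-induced Ndrg1 stood at -1.26. The immediate early list had a median of -0.35 (22 members, 9 lower and 4 higher, percentile 0.01), with the transcription factors Atf3 (-1.35) and Nr4a1 (-1.17) lower and Ier3 (0.72) higher. The NF-kB and inflammatory list had a median of -0.26 (24 members, 5 lower and 2 higher, percentile 0.37), in which Icam1 (-0.99) was lower and the chemokine Cxcl2 (1.69) and Acod1 (2.77) were higher. The interferon list had a median of 0.29 (29 members, 10 higher and 2 lower, percentile 99.3), with Ifi204 (2.22 to 14.4 CPM) and Oas1a (1.76) higher and Ifit3b (-2.42) lower. The mature neutrophil list stood at -0.17 (18 members, 4 higher and 3 lower, percentile 1.73), MHC class I presentation at -0.23 (16 members, 3 higher and 1 lower, percentile 2.15), TGF-beta response at -0.39 (13 members, 2 higher and 0 lower, percentile 0.60) and cell cycle at -0.39 (21 members, 4 lower and 1 higher, percentile 0.40). The cell cycle median turned to 0.36 when clustered without granule genes and the TGF-beta median to 0.027 with separate clustering. Oxidative phosphorylation stood at 0.26 (26 members, 6 higher, percentile 98.8).

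Lymphocyte markers were also higher among Het neutrophils. The naive lymphocyte list had a median of 1.71 there (12 members, 8 higher) and the T regulatory and exhaustion list 1.16 (6 members, 3 higher), at low levels such as 0.661 and 6.05 CPM for Lef1. Haemoglobin took 71.5% of UMIs in WT and 56.3% in Het neutrophils, and the other genes 1112 and 2152 UMIs per cell. With scaling by UMIs without haemoglobin genes, the interferon list median turned to -0.15 and that of oxidative phosphorylation to -0.18, while the granule list stood at 1.43 and hypoxia and glycolysis at 0.51. The other medians were further below 0, at -0.78 for immediate early, -0.69 for NF-kB and inflammatory, -0.67 for MHC class I, -0.60 for mature neutrophil and -0.82 for both TGF-beta and cell cycle. With plain class totals the mature neutrophil median turned to 0.014.

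**Figure D2:**
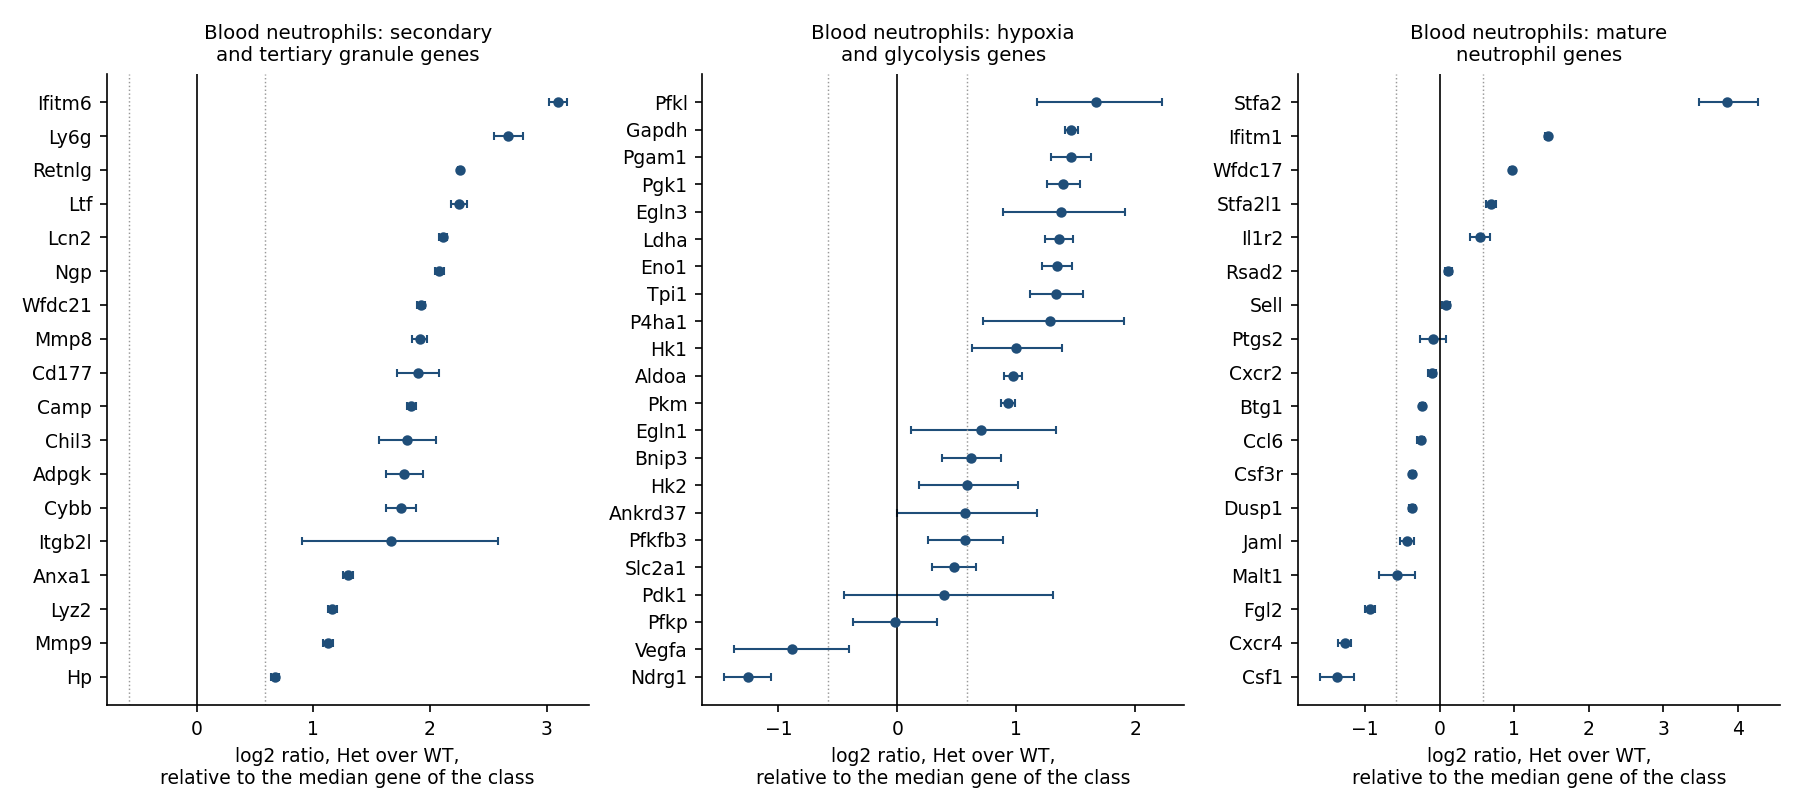
Log2 ratio of Het over WT (CPM, relative to the median gene) for secondary and tertiary granule genes, hypoxia and glycolysis genes and mature neutrophil genes (left to right) in blood neutrophils, 1 pooled library per genotype. Points are single genes, bars their 95% counting intervals, and dotted lines mark 1.5-fold. All 18 granule genes lie above 1.5-fold, with a median of 1.87, while Ndrg1 stands at -1.26 and Cxcr4 at -1.27.

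In blood T cells the naive lymphocyte list had a median of 0.30 (12 members, 2 higher and 0 lower, percentile 100), with the transcription factor Lef1 (166 to 234 CPM, log2 0.60) and Dapl1 (0.64) higher. The T regulatory and exhaustion list had a median of -0.58 (10 members, 4 lower and 0 higher, percentile 0). Foxp3, the lineage factor of regulatory T cells (-0.96), the interleukin-2 receptor gene Il2ra (-0.89) and the inhibitory receptor Ctla4 (-0.74) were lower. The cluster led by Foxp3 held 207 of 1897 WT and 236 of 3445 Het T cells. The 3 clusters led by Igfbp4, Lef1 or Cd4 held 697, 241 and 139 WT and 1212, 689 and 239 Het T cells, and the cluster led by Cxcr6 and Tcrg-C2 held 395 and 522. The naive and regulatory medians and Tcrg-C2 therefore also carry the mix of T cell subsets. Cell cycle genes had a median of -0.34 (24 members, 8 lower and 1 higher), with Top2a (-1.14) and Stmn1 (-0.82) lower and Nusap1 (1.27) higher. The interferon list stood at 0.26 (30 members, 6 higher and 2 lower, percentile 100), hypoxia and glycolysis at -0.15 (21 members, 1 lower) and oxidative phosphorylation at -0.07 (26 members, none higher or lower).

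The genes named as higher in T cells were the splicing factor Cwc22 (2.03, 15.0 to 57.5 CPM), the interferon-inducible Mndal (1.61, 31.1 to 88.6 CPM), Tagap1 (1.29), Prxl2a (1.28) and the neutrophil alarmin S100a8 (1.26). Prxl2a, also among the leading genes of the erythroid cluster, lay at 37.1 and 84.2 CPM against 41.9 and 81.3 CPM in free RNA. With the profile of low-gene blood barcodes subtracted, scaled to haemoglobin, its log2 ratio was 0.44. Those named as lower were Rgs1, a regulator of G protein signalling (-1.27), Sfi1 (-1.18), the lectin Lgals3 (-1.16, below its free RNA CPM in both libraries), Tpm3-rs7 (-1.04) and the gamma T cell receptor constant gene Tcrg-C2 (-0.96, and -2.22 with separate clustering). The cytotoxic list had a median of 0.51 (20 members, 9 higher and 2 lower), with the granzymes Gzmd at 2 UMIs in WT and 445 in Het and Gzmf at 4 and 445. In blood NK cells these went the other way, Gzmd at 946 and 1 UMIs and Gzmf at 1106 and 0, and over all blood cells they were lower in Het, at 950 and 449 and at 1113 and 452. Most UMIs of both genes thus lay in NK cells in WT and in T cells in Het, where the CD8 cluster had them among its leading genes. The T cell values of Gzmd and Gzmf therefore show no rise over blood cells as a whole. Why the UMIs lay in different classes was not tested, and the naming of cells as T cells or NK cells may enter. Over all blood cells the cytotoxic list stood at -0.26 (20 members, 7 lower and 0 higher), and with separate clustering its T cell median turned to -0.84. Granule genes of neutrophils were also higher among T cells (median 1.65, 16 members, 9 higher), and S100a8 lay at 132 and 294 CPM there against 1718 and 4057 CPM in free RNA. With the top 8% of doublet scores removed in both libraries, the medians of the granule and cytotoxic lists in T cells turned to -0.15 and -0.20 and S100a8 to -0.57.

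Monocytes or macrophages of Het blood had lower MHC class II expression. The MHC class II list had a median of -0.89 (10 members, 5 lower and 0 higher, percentile 0). H2-Aa (746 to 274 CPM, -1.47), H2-Ab1 (457 to 174 CPM, -1.42), the invariant chain Cd74 (-0.84) and the class II transactivator Ciita (-1.07) were lower, while H2-Eb1 stood at -0.17. The other genes named as lower were the interferon-inducible Ifi202b (-2.20), Wfdc17 (-1.30) and the eosinophil-associated ribonuclease Ear1 (-1.22). Those named as higher were the iron carrier transferrin Trf (1.92, 73.7 to 284 CPM), Retnlg (1.93), Mndal (1.68), Cwc22 (1.68) and the lipid flippase Atp11b (1.56). MHC class I presentation stood at -0.16 (16 members, 1 lower) and the NF-kB and inflammatory list at -0.14 (25 members, 4 lower and 1 higher), with Ccl3 at 31.0 and 15.8 CPM and Il1b at -0.87. Markers of other cells were higher here too. The naive lymphocyte list had a median of 1.69 (12 members, 9 higher) and the granule list 0.63 (17 members, 8 higher and 1 lower), and Retnlg lay below its free RNA level of 286 and 812 CPM. With separate clustering Retnlg stood at 3.95. Trf lay below free RNA only in WT and Wfdc17 only in Het. With no doublet removal in either library the naive lymphocyte median was 0.74.

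Over all blood cells the granule list stood at 1.72 (18 members, 16 higher), the primary granule list at 0.47 (6 members, 2 higher, percentile 99.8), the interferon list at 0.21 (30 members, 7 higher and 3 lower), MHC class II at -0.27 (10 members, 2 lower and 1 higher), cell cycle at -0.48 (24 members, 8 lower and 1 higher) and T regulatory and exhaustion at -0.43 (11 members, 2 lower). The glucocorticoid response list stood at -0.10 (18 members, 2 lower and 1 higher, percentile 1.61), and turned to 0.034 in cells with under 50% haemoglobin UMIs. Genes near Htr1a on chromosome 13 stood at -0.04 (28 members, percentile 20.5). These medians mix differences in cell shares with differences within cells.

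In decidua, NK cells and macrophages made up a smaller share of the Het library. NK cells were 4.51% of WT nuclei (4.11 to 4.94) and 2.31% of Het nuclei (2.05 to 2.60), a log2 ratio of -0.96 (-1.19 to -0.74). Monocytes or macrophages were 2.73% and 1.21% (-1.18, -1.48 to -0.88). Decidual stromal nuclei, the differentiated cells of the implantation site, were 49.7% and 52.0% (0.07) and endothelial nuclei 12.2% and 12.4% (0.02). Pericytes were 0.484% and 0.746% (0.62, 0.10 to 1.16), spongiotrophoblast or glycogen cells, which are of fetal origin, 0.453% and 1.53% (1.75, 1.27 to 2.26), and unnamed nuclei 30.0% and 29.9%. An unnamed cluster close to stromal nuclei, led by Col12a1, Tmem45a and F13a1, held 10.5% of WT nuclei and 2.46% of Het nuclei (-2.09). A stromal cluster led by the interferon-induced Rsad2, Ifit1 and Iigp1 held 0.584% and 0.163%. With WT nuclei thinned to 0.723 of their UMIs and the UMI minimum applied again, 9509 WT nuclei with a median of 2788 UMIs were left, against 2703 UMIs in Het. The macrophage ratio then shrank to -0.43 (-0.77 to -0.09) and the NK ratio was -0.94 (-1.17 to -0.72). With WT nuclei thinned to 0.693, for a median of 2682 to 2689 UMIs, the upper bound lay below 0 in 2 of 20 random draws for macrophages and in 20 of 20 for NK cells. Nuclei kept their classes in both thinnings. The stromal ratio turned negative under several alternatives, reaching -0.66 with each library clustered on its own.

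In decidua the interferon list had a negative median in each of the 3 largest named classes. In stromal nuclei the interferon list had a median of -0.46 (30 members, 10 lower and 1 higher, percentile 0), with Ifi204 (24.98 to 5.74 CPM, -2.12), the antiviral Rsad2 (-1.62) and Ifit1 (-1.21) lower. The cluster led by Rsad2 and Ifit1 (58 WT and 19 Het nuclei) is part of this class. Without it the median was -0.26 (30 members, 7 lower and 1 higher, percentile 0), with Rsad2 at -0.70, Ifit1 at -0.85 and Ifi204 at -2.08. With the UMI minimum and no free RNA test the median of the class was -0.22. In endothelial nuclei it was -0.33 (30 members, 9 lower and 2 higher, percentile 0) and in NK nuclei -0.39 (24 members, 1 lower, percentile 0.02). Over all nuclei it was -0.51 (30 members, 13 lower, percentile 0), and the only member higher was Ifi213 (0.481 to 5.17 CPM, 3.39). Values over all nuclei mix differences in class shares with differences within classes. MHC class I presentation stood at -0.20 in stromal nuclei (16 members, 4 lower), -0.52 in endothelial nuclei (16 members, 7 lower), -0.15 in NK nuclei (16 members, 0 lower, percentile 4.46) and -0.44 over all nuclei (16 members, 7 lower). Over all nuclei the class I gene H2-Q7 (25.7 to 8.70 CPM, -1.57), the class I transactivator Nlrc5 (-1.15), H2-D1 (-0.61) and the class I light chain B2m (-0.61) were lower. MHC class II stood at -0.56 in stromal nuclei (7 members, 3 lower), 0.37 in NK nuclei (4 members, none higher or lower) and -0.71 over all nuclei (8 members, 5 lower), where the smaller share of macrophages (2.73% and 1.21%), which carry these genes, also enters. That median was -2.29 with free RNA subtracted and -0.38 with the higher UMI minimum.

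**Figure D3:**
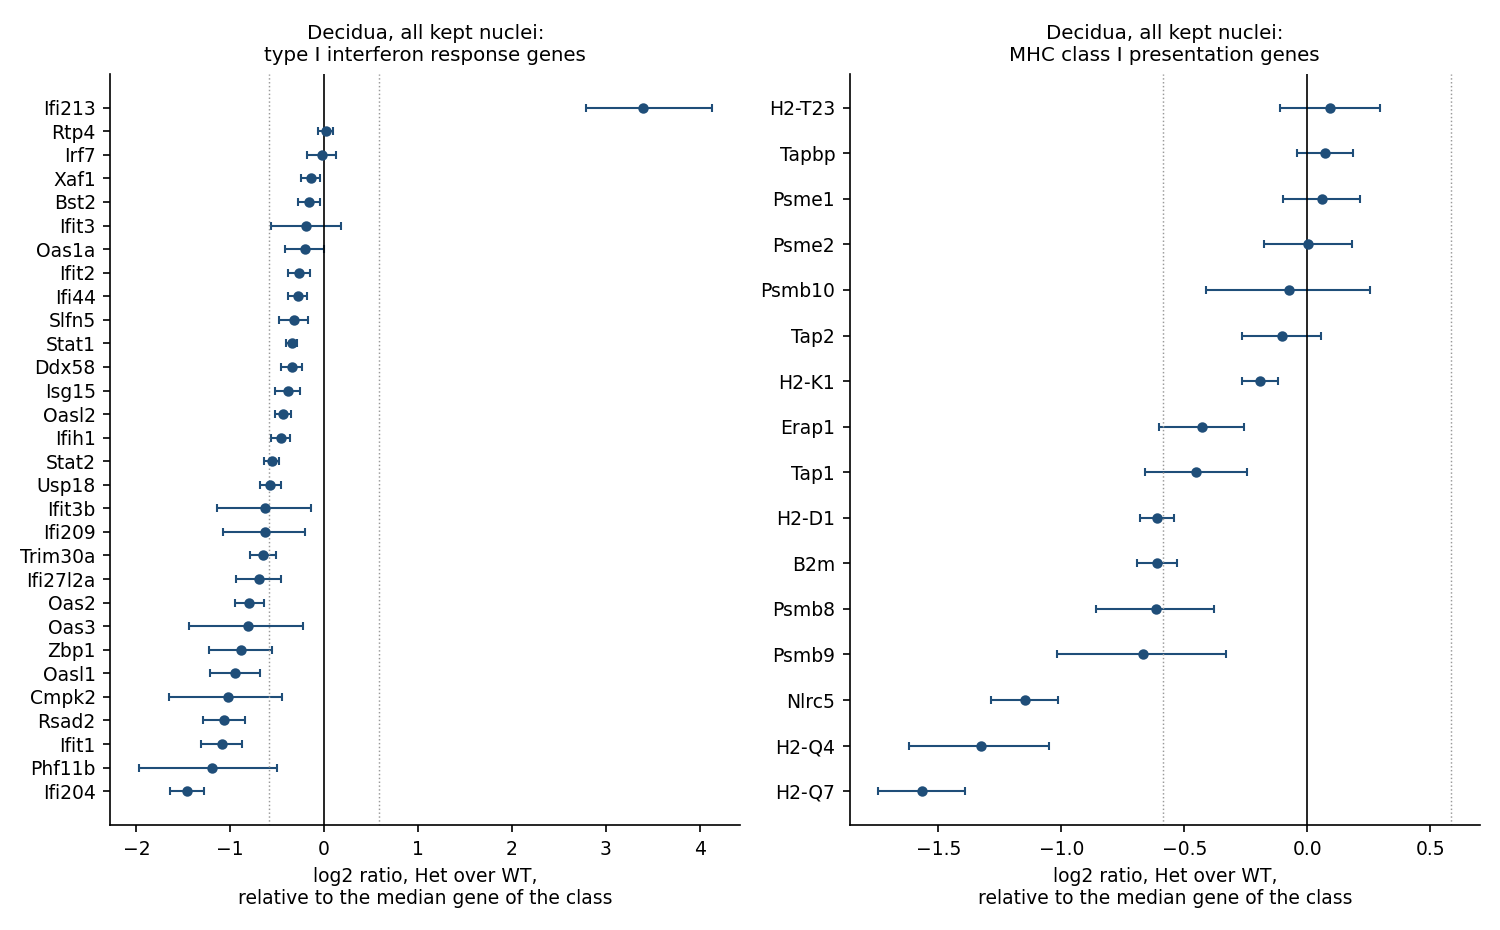
Log2 ratio of Het over WT (CPM, relative to the median gene) for interferon response genes (left) and MHC class I presentation genes (right) over all kept decidual nuclei, 1 pooled library per genotype. Points are single genes, bars their 95% counting intervals, and dotted lines mark 1.5-fold. Ifit1 stands at -1.09 and H2-Q7 at -1.57, while Ifi213 lies at 3.39.

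The genes named as lowest in stromal nuclei of the Het decidua were Syn2, a synaptic vesicle gene (57.4 to 1.40 CPM, -5.34, -5.99 to -4.81), the collagen gene Col6a3 (88.8 to 12.3 CPM, -2.85), the matrix protein periostin Postn (-1.92), the adhesion gene Nrxn3 (-1.88) and the cation channel gene Trpc4 (-1.59). Col6a3 lay below free RNA in Het. The mix of stromal clusters also differed and enters these ratios. Among clusters of over 500 nuclei the log2 ratios of the shares included -0.84 (led by Igf1), -0.35 (led by Nrxn3) and 0.65 (led by Atoh8), and the small cluster led by Rsad2 held 0.584% and 0.163%. With separate clustering Trpc4 stood at -3.56 and Cd244a at 3.07. The extracellular matrix list stood at -0.02 (30 members, 4 lower and 2 higher). Those named as highest were Cda, cytidine deaminase (6.46 to 139 CPM, 4.42, 4.17 to 4.69), the immune receptor gene Cd244a (4.27), Tpbpa (2.68), Kank3 (2.49) and the ubiquitin gene Ubb (2.42). All 5 of these also had higher free RNA levels in Het. Cda (free RNA 17.5 and 146 CPM), Kank3, Ubb and the trophoblast marker Tpbpa (30.2 and 194 CPM against 266 and 722 CPM) lay below free RNA in both libraries, and Cd244a only in WT. The decidualization list had a median of 0.11 (28 members, 3 higher and 2 lower, percentile 99.8), with Wnt4 (13.9 to 40.9 CPM, 1.55) and the decidual prolactin Prl8a2 (0.99) higher and Il11ra1 (-1.62) and Cryab (-1.21) lower. The angiogenesis list stood at 0.13 (25 members, 2 higher), heat shock and chaperones at 0.29 (14 members, 1 lower, percentile 100), oxidative phosphorylation at 0.19 (26 members, none higher or lower, percentile 100) and hypoxia and glycolysis at 0.12 (24 members, none higher or lower). With free RNA subtracted the angiogenesis median turned to -0.15 and that of heat shock to -0.025. The cytotoxic list stood at -0.46 (18 members, 5 lower), with Gzmd at 97.6 and 62.1 CPM, and the naive lymphocyte list at -0.34 (10 members, 1 lower). NK nuclei were 4.51% of WT and 2.31% of Het nuclei, and whether their RNA enters the cytotoxic median was not tested. Steroid hormone signalling and synthesis stood at 0.04 (16 members, 1 higher), immune recruiting ligands at -0.14 (18 members, 2 lower) and genes near Htr1a at -0.02 (27 members, 2 higher and 1 lower).

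Endothelial nuclei of Het decidua had higher Setbp1 (29.2 to 193 CPM, 2.73), Tpbpa (2.66), Slc35f3 (2.05), Ubb (1.92) and Prl2b1 (1.74), a placental prolactin. They had lower Tmem117 (-2.24), the adhesion genes Nrxn3 (-2.23) and Nrxn1 (-2.12), the zinc finger gene Zfp949 (-1.89) and the ubiquitin ligase gene Mid1 (-1.40). Slc35f3 was the first leading gene of an endothelial cluster that held 276 of 1209 WT and 491 of 1444 Het endothelial nuclei, so the mix of clusters enters its ratio. Setbp1, Tpbpa, Ubb, Prl2b1 and Nrxn3 lay below their free RNA CPM in both libraries, where Nrxn3 was also lower in Het (199 and 72.9 CPM), and Zfp949 did so only in Het. The angiogenesis list stood at 0.10 (24 members, 3 higher and 1 lower), with the growth factors Pgf (1.06) and Apln (0.95) higher and Vegfc (-1.02) lower. TGF-beta response stood at 0.22 (18 members, 2 higher, percentile 99.9), with Inhba (1.64) and Pmepa1 (0.80) higher. Hypoxia and glycolysis stood at 0.27 (23 members, 1 higher, percentile 100), heat shock at 0.23 (14 members, 1 higher and 1 lower), oxidative phosphorylation at 0.19 (26 members, 1 higher) and immediate early genes at 0.18 (21 members, 4 higher and 1 lower). The cytotoxic list stood at -0.60 (14 members, 7 lower and 0 higher, percentile 0), with Gzmf at 138 and 73.0 CPM. NK nuclei were 4.51% of WT and 2.31% of Het nuclei. The members Prf1 and Gzmb had 95 and 45 and 18 and 10 UMIs in free RNA of WT and Het. Whether RNA of NK cells enters this median was not tested. Genes near Htr1a stood at -0.16 (25 members, 1 higher and 0 lower, percentile 0.24).

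Decidual NK nuclei were few, 448 in WT and 270 in Het, and their intervals wide. Klrb1b, an inhibitory NK receptor gene, was at 8 UMIs in WT and 102 in Het (4.91, 3.96 to 6.24), and its neighbour Klrb1c at 7 and 29 (3.29). Both genes, and the NK receptor gene Klra7, were higher in Het by the size rule in NK cells of blood as well as of decidua. Mndal (4.24), Tpbpa (2.81), Lsamp (2.76) and Rimklb (2.44) were also named as higher, of which the last 3 lay below their free RNA CPM. With the UMI minimum and no free RNA test, Lsamp stood at 0.18 and Rimklb at 0.35 in NK nuclei, under 1.5-fold, and both were leading genes of an unnamed cluster that held 3.23% of WT and 6.22% of Het nuclei. Mid1 (-2.41), Lrp5 (-2.13), the adhesion gene Chl1 (-2.12), Zfp949 (-2.03) and Sugct (-1.76, 836 to 246 CPM) were named as lower. Mid1 lay below its free RNA CPM in both libraries, where it was also lower in Het (148 and 79.7 CPM), and Zfp949 only in Het. The cytotoxic list was close to level inside this class at -0.14 (18 members, 1 higher and 0 lower, percentile 20.2), with perforin Prf1 at 747 and 829 CPM, while over all decidual nuclei it stood at -0.69 (19 members, 9 lower and 0 higher). Heat shock genes stood at 0.38 (12 members, 1 higher and 1 lower, percentile 100) and oxidative phosphorylation at 0.27 (26 members, 3 higher, percentile 99.1). In simulated data for this class an unchanged list of 20 genes reached percentile 1.08.

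Over all decidual nuclei heat shock stood at 0.35 (14 members, 2 higher and 1 lower), oxidative phosphorylation at 0.19 (26 members, none higher or lower), angiogenesis at 0.12 (25 members, 3 higher and 1 lower) and T regulatory and exhaustion at -0.38 (11 members, 4 lower). With free RNA subtracted these heat shock and oxidative phosphorylation medians turned to -0.73 and -0.82 and that of angiogenesis to -0.044, and with the higher UMI minimum the angiogenesis median was -0.035. The Y-linked list, which marks male fetal cells, stood at 0.80 (4 members, 3 higher).

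**Figure D4:**
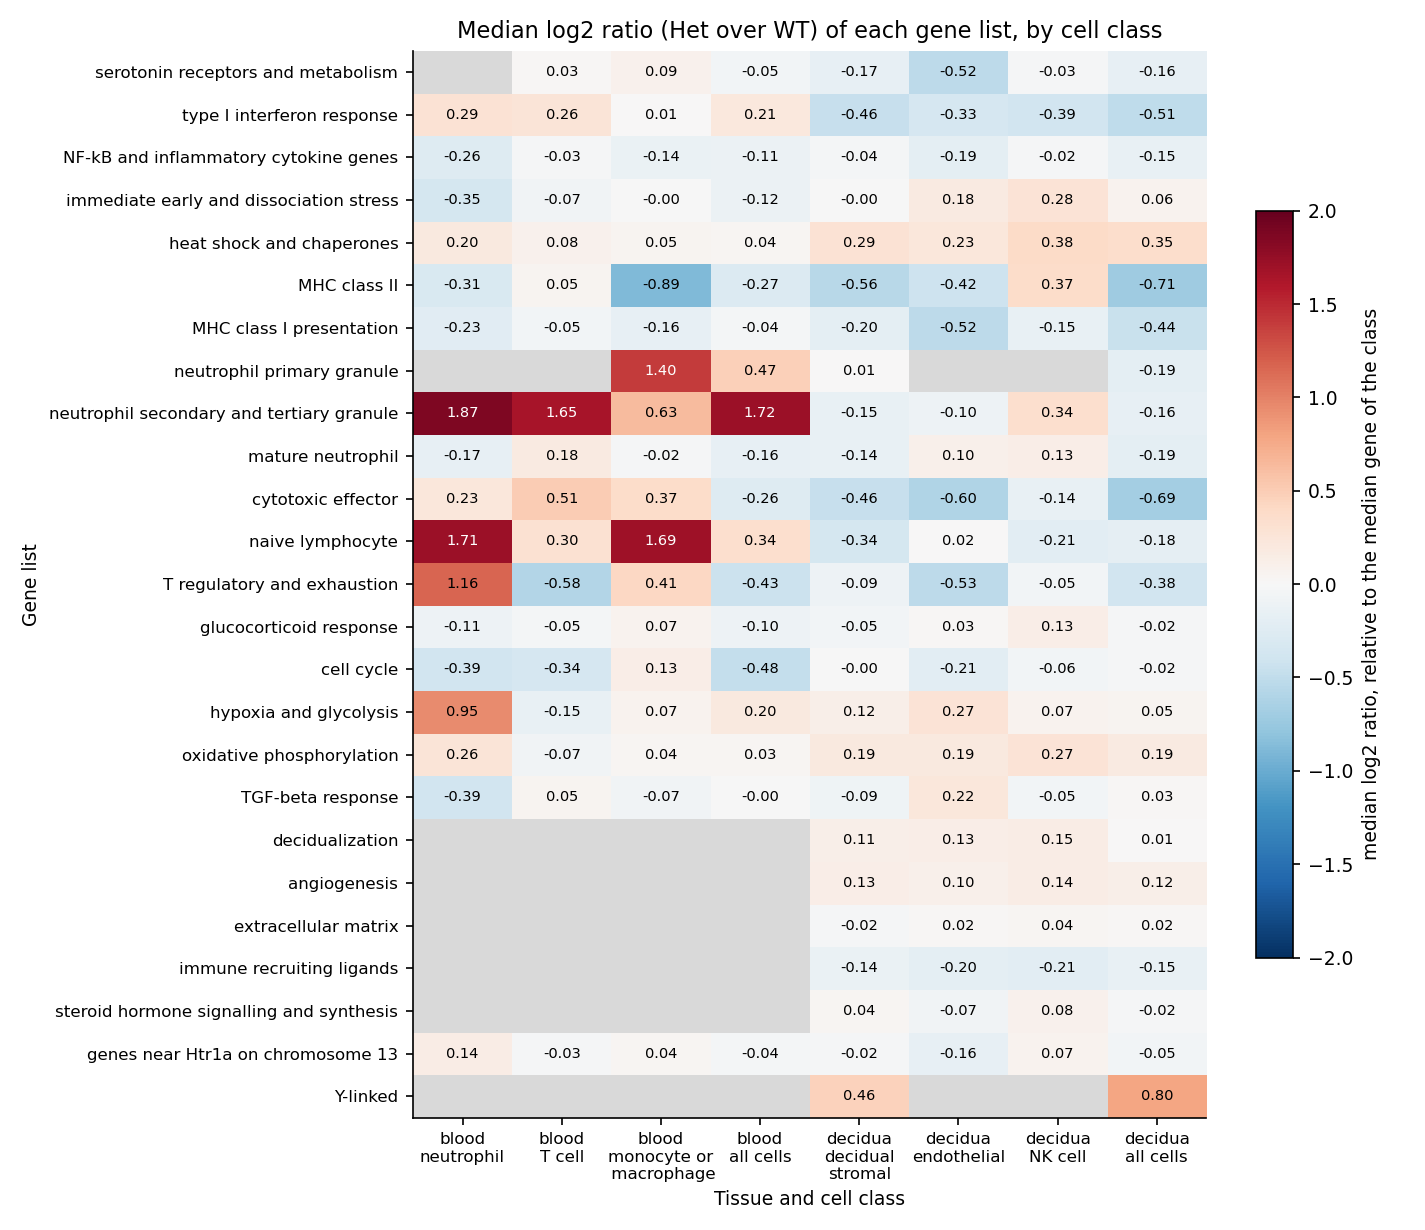
Median log2 ratio of Het over WT of each gene list (rows) in the 3 largest named classes and in all kept cells of each tissue (columns), 1 pooled library per genotype. Colour gives the median, and grey marks lists with fewer than 3 members measured or not used in that tissue. The granule list stands at 1.87 in blood neutrophils and the interferon list at -0.46 in decidual stromal nuclei.

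Classes present in both tissues were compared across genes, which are not independent replicates. The log2 ratios of blood and decidua had a Spearman correlation of -0.00409 in NK cells (6007 genes, 49.1% with the same sign) and 0.07 in monocytes or macrophages (4263 genes, 53.3%). A rule chosen after the data were seen asked for the same direction by at least 1.5-fold in 3 or more classes of each tissue. It was met by Mndal (ENSMUSG00000090272, mm10 chromosome 1, 173849126 to 173942491), Cwc22 (ENSMUSG00000027014, chromosome 2, 77881159 to 77946375) and Tmem14c (ENSMUSG00000021361, chromosome 13, 41016292 to 41022586), of 6340 genes, with 0 genes in opposite directions. The rule had first asked for 2 classes of each tissue and was tightened after its outcome was seen. At 2 classes it is met by 8 of 8618 genes, with 2 in opposite directions. These 8 are Mndal, Cwc22, Tmem14c, Ifi213, H2-Q4, Wnt4, Ggt1 and AA465934. Mndal and Cwc22 were higher in Het, with log2 ratios from 1.503 to 4.15 and from 1.41 to 2.15 in blood and from 2.15 to 4.24 and from 1.31 to 1.74 in decidua. Tmem14c, a mitochondrial porphyrin transporter, was lower, from -1.11 to -0.60 in blood and from -2.51 to -1.20 in decidua. Of the other named genes, Prok2 (ENSMUSG00000030069), the highest in blood neutrophils, lies on chromosome 6 from 99711299 to 99726392, and Syn2 (ENSMUSG00000009394), the lowest in decidual stromal nuclei, on chromosome 6 from 115134902 to 115282006.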

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

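The tests of haemoglobin, free RNA, doublets, fraction recovery, added fetal nuclei, dissected region, chance, interferon response and a strain variant were chosen only after the results they address were seen, and those of depth and cell calling after the shares but before the values they measure. The stricter thinning for depth, and the rule that all its draws must agree, were added after the first thinning was seen.

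The NK cell share had opposite log2 ratios in the 2 tissues, 0.31 in blood and -0.96 in decidua, and the difference was not tested. The blood share is taken of cells that include neutrophils (43.8% of WT and 29.3% of Het), which were prepared in another fraction. A smaller neutrophil share by itself raises the NK share of blood. The interferon list also had opposite medians over all kept cells, 0.21 in blood and -0.51 in decidua, and this difference was not tested either. Barcodes with 100 or fewer UMIs held Ins2, the insulin gene of pancreatic beta cells, at 35430 CPM in blood WT and 37242 CPM in blood Het, against 0.759 and 4.24 CPM in decidua WT and Het. Y-linked genes, which maternal cells lack, were counted in kept nuclei with 385 UMIs in decidua WT and 603 UMIs in decidua Het, against 4 and 3 in blood. They lay highest in spongiotrophoblast or glycogen cells, at 311 and 343 CPM.

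Granule genes were higher in Het blood neutrophils. Among neutrophils with under 50% haemoglobin UMIs (1196 WT and 1698 Het cells) the list median was 1.46, and with no doublets removed in either library it was 1.80, which argues against haemoglobin load and unequal doublet removal as the whole cause. For 18 of 18 members the rise in CPM without haemoglobin genes was larger in neutrophils than in free RNA, which argues against free RNA as the whole cause. The neutrophil share of named leukocytes also differed (-0.44), so a different recovery of the 2 blood fractions, and with it of neutrophil stages, cannot be told apart from an effect of genotype with 1 pool per group. A shift toward younger neutrophils in Het females may be involved and stays open.

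NK and macrophage shares were lower in Het decidua. With WT nuclei thinned to a median of 2788 UMIs, against 2703 in Het, the upper bounds of the log2 ratios were -0.72 for NK cells and -0.093 for macrophages, and the macrophage ratio shrank from -1.18 to -0.43. With a stricter thinning, to a median of 2682 to 2689 UMIs, the bound stayed below 0 in 20 of 20 random draws for NK cells but in 2 of 20 for macrophages. Depth was therefore not the whole cause for NK cells, and for macrophages the thinning did not decide. Over all barcodes, with no UMI minimum or cell calling, the class markers had medians of -1.14 (NK, 8 of 9 lower) and -0.79 (macrophage, 12 of 12 lower). These values argue against cell calling, and against nuclei lost below the UMI minimum as the whole cause for macrophages. How much depth adds to the macrophage ratio stays open. Added fetal nuclei would lower the shares of stromal-like nuclei as much. Among NK and stromal-like nuclei the upper bound of the NK ratio was -0.62, and -0.76 for macrophages counted likewise, which argues against added fetal nuclei as the whole cause. An unnamed cluster differed by -2.09, so a different region of decidua in the 2 pools could contribute and cannot be told apart from genotype. An effect of maternal or fetal genotype stays open as untested.

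Mndal, Cwc22 and Tmem14c differed the same way in both tissues. Against these 3 genes, 0 genes met the same rule in opposite directions, too few to judge chance, and at 2 classes of each tissue, the rule first tried, 8 genes met it and 2 in opposite directions. The interferon list without its chromosome 1 genes had a median of -0.46 in all decidual nuclei, which argues against an interferon response as the source of higher Mndal in decidua. In blood that list stood at 0.16 over all cells and -0.014 in monocytes, so there an interferon response stays open. A first test of a strain variant, for pairs of these 3 genes within 1 Mb, found 0 and decided nothing. The 8 genes met at 2 classes do hold such a pair, Mndal and Ifi213 on chromosome 1. Both are interferon-inducible genes of 1 cluster, and the rule was tightened after its outcome was seen, so this pair does not decide either. The first test was then replaced by another, in which 8 of 8 pairs of gene and class, of classes not used to pick the genes, differed the same way. Trophoblast was moved to those classes for this test, and unnamed cells resemble named ones. Inherited variants that differ between the pools are a candidate explanation, but without reads they cannot be told apart from other differences between the pools.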

How the results depend on the processing

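No paired analysis was possible because each group has 1 library. Chosen after the data were seen were the alternatives with named leukocytes or non-trophoblast nuclei as denominator, UMIs without haemoglobin genes, cells under 50% haemoglobin, the top 8% of doublet scores removed, clustering without granule genes, and the shortened interferon list. The cause was not tested for any value below.

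Blood class shares stayed within counting error in 86 of 105 comparisons with an alternative, moved in 18 and reversed in 1. Blood named genes did so in 322, 67 and 1, decidua shares in 51, 9 and 5, and decidua named genes in 307, 53 and 0. Blood gene lists stayed within their band in 1013, moved in 64 and reversed in 15, and decidua gene lists in 1321, 8 and 8. That band runs between the medians of the members' lower and upper bounds and is no interval of the list median. A turn of sign counted as reversed only for shares with an interval off 0, lists outside the range of random lists, and named genes. Values of Htr1a stayed within counting error in 44 of 44. Those of the correlation between tissues moved by at most 0.05, a set limit and no error, in 4 of 4.

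The T cell ratio was 0.29 with the UMI cut alone, 0.27 with separate clustering and 0.55 of named leukocytes. The neutrophil ratio was -0.49 with the higher UMI minimum, -0.45 with the UMI cut alone, -0.45 with the lower mitochondrial limit and -0.44 of named leukocytes. The erythroid ratio was 1.51 with the lower UMI minimum, 1.45 at resolution 2, 0.78 with separate clustering and 1.41 with the top 8% removed. The platelet ratio was 0.31 with separate clustering.

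In neutrophils the granule median was 2.05 with plain totals, 1.43 without haemoglobin UMIs, 1.74 with the higher UMI minimum, 1.75 with separate clustering and 1.46 in cells under 50% haemoglobin. Without haemoglobin UMIs interferon was -0.15 and oxidative phosphorylation -0.18. The mature list was 0.014 with plain totals, cell cycle 0.36 when clustered without granule genes, and TGF-beta 0.027 with separate clustering. In T cells, with the higher UMI minimum, no doublet removal and the top 8% removed, the granule median was 0.30, 0.30 and -0.15 and the mature neutrophil median -0.21, -0.23 and -0.16. The T cell cytotoxic median was -0.0068 with the higher UMI minimum, -0.84 with separate clustering and -0.20 with the top 8% removed, and S100a8 was -0.57 with the last. In monocytes the naive median was 0.75 with the higher UMI minimum and 0.74 with no doublet removal. Over blood cells under 50% haemoglobin, immediate early was 0.032, mature neutrophil 0.18 and glucocorticoid 0.034.

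The decidual NK ratio was -1.39 with the higher UMI minimum, -1.43 with the UMI cut alone and -1.36 with no free RNA test. The macrophage ratio was -0.49 with the lower and -1.50 with the higher UMI minimum. The stromal ratio was -0.28 with the higher UMI minimum, -0.027 with the UMI cut alone, 0.13 with no free RNA test, -0.16 at resolution 0.5, -0.10 at resolution 2 and -0.66 with separate clustering. With free RNA subtracted, stromal heat shock was -0.025 and angiogenesis -0.15, and over all nuclei heat shock was -0.73, mature neutrophil 0.11, oxidative phosphorylation -0.82 and angiogenesis -0.044. Endothelial decidualization was -0.0078 with a minimum of 50 UMIs, and angiogenesis over all nuclei -0.035 with the higher UMI minimum.

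With separate clustering the B cell ratio was -4.05, and the plasma cell and decidual macrophage shares had no value. The trophoblast share had none with the lower or higher UMI minimum, the UMI cut alone, resolution 0.5 or separate clustering, since no cluster was named. With a minimum of 50 UMIs, or with free RNA subtracted or the deeper library thinned, several lists kept under 3 members and had no median: primary granule, T regulatory, serotonin, MHC class II, Y-linked and, in NK nuclei, secondary granule.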

Other observations

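Interferon-inducible genes of 1 cluster on chromosome 1 differed apart from each other. Over all kept cells the log2 ratios in blood and decidua were 1.69 and 2.29 for Mndal, 1.76 and 3.39 for Ifi213, 0.65 and -1.46 for Ifi204, 0.22 and -1.55 for Ifi207, and -2.15 and -1.42 for Ifi202b.

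Barcodes with 10 or more UMIs of pancreatic islet hormone genes, a list written after Ins2 was seen, numbered 9907 in blood WT and 11567 in blood Het. Of these, 7402 barcodes were shared between the libraries, against 16.9 expected from barcodes drawn at random. Kept cells shared 35 barcodes, against 19.1 expected.

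Unnamed blood clusters in which neutrophil genes appeared beside those of T cells, B cells or monocytes held 11 WT and 140 Het cells, 2 and 44 cells, and 1 and 30 cells.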
